A study of Mus musculus with 30 samples.

How the data were processed

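The series measured RNA in 30 cultures of mouse fetal testis. Testes of C57BL/6 fetuses were taken on gestational day 14, separated from the mesonephros and kept on culture inserts for 24 h with a treatment or its DMSO vehicle. Groups were taken from the treatment label of each sample, which gave 15 vehicle libraries, 6 with mono-(2-ethylhexyl) phthalate (MEHP, 100 µM), 5 with all-trans retinoic acid (ATRA, 1 µM) and 4 with both compounds at the same doses (MEHP + ATRA). Libraries were made from poly(A)-enriched RNA with a NEBNext Ultra II kit, per the labels' protocols.

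The deposited values are raw counts per gene, 1 file per library, in the layout that featureCounts writes, per the file headers. Per the submitters' processing notes, the authors used bcl2fastq 2.20, Trimmomatic 0.36, STAR 2.5.2b, featureCounts from Subread 1.5.2, and DESeq2 with no version. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. The files hold 49315 Ensembl mouse genes. Symbols were taken by gene identifier from a separate list of gene names, which covered 99.3% of identifiers. Gene types were taken from GENCODE M21 (GRCm38) by gene identifier, and 99.47% of identifiers matched. Of the matched genes, 91.37% had the same chromosome, start and end as that annotation and 99.87% started within the same 100 kb, so coordinates are printed as the files give them, on a GRCm38 frame. Because the strand setting is not given, reads of genes that overlap on opposite strands cannot be told apart. Counting could also have split reads between near-identical copies, such as pseudogenes and the globin genes. Every per-sample column belonged to a labelled sample.

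Sample titles hold 2 numbers whose meaning is not stated. The second number fell in a lower range (416 to 465) or an upper range (525 to 599). All 6 MEHP libraries were in the upper range, all 5 ATRA and all 4 MEHP + ATRA libraries were in the lower range, and vehicle libraries were in both (9 lower, 6 upper). A range term was therefore fitted, which set each treatment against the vehicle libraries of its own range. Nothing in the labels says whether libraries came from separate animals or litters, so p-values measure only the spread between these libraries. Each of the 9 first numbers within a range held as many treated as vehicle libraries, so a pairing by this number is possible. The main fit takes no account of one, and fits with a block on the first number are given as alternatives.

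Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 19323 genes. Libraries were scaled by TMM, with factors from 0.975 to 1.023. One quasi-likelihood model over all 30 libraries held the 4 groups and the range, with 25 residual degrees of freedom. The common biological coefficient of variation was 12.7%. Tests were quasi-likelihood F tests, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. Adjusted p-values in the text are from this edgeR test unless a list test is named. The 7 contrasts tested were each treatment against vehicle, MEHP + ATRA against ATRA and against MEHP, the interaction (the MEHP effect with ATRA minus the MEHP effect without it), and the difference between ranges in vehicle. Levels are CPM (library-scaled counts) after TMM scaling, as mean ± SD.

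Gene lists fixed before the data were examined, 24 in all, covered PPAR targets and fatty acid oxidation, cholesterol biosynthesis, Leydig cells and steroidogenesis, retinoic acid response, meiosis, germ cells, male germ cell differentiation, pluripotency, Sertoli cells, ovarian somatic cells, peritubular myoid and smooth muscle cells, interstitial progenitors, Hedgehog response, anterior Hox genes, endothelium, macrophages, erythroid cells, mesonephros, proliferation, immediate early genes, hypoxia and glycolysis, ATF4 and the unfolded protein response, NRF2 targets and p53 targets. Of their 408 distinct genes, 400 were tested. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 24 lists, and again with the correlation estimated per list. Members were counted from the gene test, over all genes and adjusted over the list alone.

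The rule for named genes was also fixed before the data were examined. It took the 8 largest rises and 8 largest falls of each treatment against vehicle among called genes with a mean log2 CPM of at least 1 and a symbol that is not a clone name. It took 5 of each for the interaction and for MEHP + ATRA against ATRA, and 3 of each for the range term. It added up to 4 members with the smallest p of each list called at the preset correlation, and a panel of 24 genes whatever their result. A gene named by 2 parts counts under both. Some genes that this rule takes, 1 of the panel among them, are not reported here.

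The tests were tested on simulated data with 200 changed genes per comparison. Changed genes were drawn only from those with a vehicle mean of at least 2 CPM, and libraries were simulated as independent. Recovery of genes at lower levels was thus not measured. At 1.5-fold they recovered 84% of changed genes for MEHP, 86% for ATRA, 77% for MEHP + ATRA and 53% for the interaction. At 2-fold they recovered 96%, 97%, 96% and 86%. Among 136 pairs of libraries of the same group, the smallest chi-square per degree of freedom was 2.64, so no pair differed by as little as sampling noise.

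Alternatives were DESeq2 1.42.0 with the same design, limma-voom with sample weights, DESeq2 size factors, no filter or at least 1 CPM in at least 4 libraries, no range term (with edgeR and with DESeq2), only the libraries of the comparison, a replicate block on the first number in the titles, the estimated inter-gene correlation, and leaving out each library in turn. A replicate block on the first number within each range, the estimated correlation with each library left out and a germ cell maturity score as a covariate were added after the data were seen. The score was computed per library from 1237 of the genes that varied most within groups and had an adjusted p over 0.2 in every treatment against vehicle and in the range contrast. Other splits of the same libraries were drawn, 100 per comparison and 50 for the interaction. Permutation tests used 100000 draws and were two-sided.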

Results

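Gene expression was measured by RNA sequencing in 30 fetal mouse testis cultures exposed for 24 h to vehicle (n = 15), the phthalate monoester MEHP at 100 µM (n = 6), the retinoid ATRA at 1 µM (n = 5) or both (n = 4). MEHP is the hydrolysis product of the plasticizer di-(2-ethylhexyl) phthalate, and ATRA is the active form of vitamin A that binds retinoic acid receptors. The design asked what each compound changed in the fetal testis and whether the effect of one depended on the other. Libraries held 17551454 to 29306917 counts in total. The range was 17787871 to 20680365 in MEHP, 18580209 to 26955598 in ATRA, 21463109 to 24038103 in MEHP + ATRA and 17551454 to 29306917 in vehicle libraries. Of 19323 genes tested, 912 changed with MEHP, 3494 with ATRA and 5595 with MEHP + ATRA, in the fit without a block on title numbers.

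MEHP raised genes of lipid metabolism. Of 25 cholesterol biosynthesis genes, 23 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 fold change of 0.48 and an adjusted p = 8.08e-05 with an estimated correlation (camera). Mvd rose by 0.97 ± 0.08 (log2 fold change ± SE), Acat2 by 0.77 ± 0.09, Sc5d by 0.69 ± 0.08, Lss by 0.68 ± 0.08 and Hmgcs1 by 0.47 ± 0.08. Of 32 tested PPAR target and fatty acid oxidation genes, 15 rose and 0 fell (15 and 1 adjusted over the list alone; adjusted p = 7.16e-05 with an estimated correlation). Angptl4, which encodes an inhibitor of lipoprotein lipase (ENSMUSG00000002289, chromosome 17, 33773750 to 33781575), rose from 52.4 ± 3.4 CPM in the upper-range vehicle libraries (SD, n = 6) to 137 ± 15 CPM (n = 6), or by 1.39 ± 0.07 in log2 (adjusted p = 4.4e-14, edgeR). Cpt1a rose by 0.61 ± 0.07 and Hadha by 0.40 ± 0.05. Other members of this list did not pass the test, among them Pdk4 (0.36 ± 0.16, adjusted p = 0.292).

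Among called genes with a mean log2 CPM of at least 1, the largest rise with MEHP was that of Stra8, the retinoid-induced gatekeeper of meiosis (ENSMUSG00000029848, chromosome 6, 34920163 to 34939344). It rose by 2.05 ± 0.42 (adjusted p = 0.0021, edgeR), from 2.57 ± 1.0 CPM to 10.5 ± 5.4 CPM, and 5 of 6 MEHP libraries lay above all upper-range vehicle libraries. Lower-range vehicle libraries held 1.24 to 9.04 CPM of Stra8, which overlaps the 2.91 to 19.5 CPM of the MEHP libraries. The highest MEHP value was in replicate 1 and the lowest in replicate 4. These lay at −30.6 and 48.8 on the axis of germ cell genes described below. The next largest rises were those of Slc25a34 (1.85 ± 0.16), Scn3b (1.84 ± 0.25), Bik (1.72 ± 0.15), Cytip (1.69 ± 0.17), Tspan32 (1.68 ± 0.18), Sowahd (1.65 ± 0.21) and Diras2 (1.59 ± 0.16). The largest falls were those of Asic4, a member of the acid-sensing ion channel family (−2.66 ± 0.19, ENSMUSG00000033007, chromosome 1, 75450436 to 75474343), the fatty acid elongase gene Elovl2 (−2.43 ± 0.15) and Miox, which encodes inositol oxygenase (−2.29 ± 0.26). Asic4 fell from 13.1 ± 3.1 CPM to 2.08 ± 0.49 CPM, with all 6 MEHP libraries below all 6 vehicle libraries. Cabp1 (−1.72 ± 0.15), Slc13a2 (−1.66 ± 0.16), Minar1 (−1.62 ± 0.25), Sgpp2 (−1.37 ± 0.14) and Kcng2 (−1.37 ± 0.21) also fell. Slc13a2 overlaps the antisense gene Slc13a2os, and their reads cannot be told apart here.

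Of 25 retinoic acid response genes, 4 rose with MEHP and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.00334 with an estimated correlation). The retinaldehyde reductase gene Dhrs3 rose by 0.57 ± 0.07. Aldh1a1, which encodes a retinaldehyde dehydrogenase, fell by 0.34 ± 0.09 in log2 (adjusted p = 0.0157), and its call was lost without MEHP replicate 1 (adjusted p = 0.0599). Cyp26a1, which encodes the retinoic acid hydroxylase, stood at 0.267 ± 0.087 CPM with MEHP and 0.152 ± 0.11 CPM in vehicle (0.78 ± 0.63, adjusted p = 0.649), a level of few reads. Rarb, a retinoic acid receptor gene and retinoid target, had 0.56 ± 0.20 (adjusted p = 0.132).

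In the somatic and germ cell markers, MEHP moved individual genes. Amh, the anti-Müllerian hormone gene of Sertoli cells, fell by 0.63 ± 0.15 in log2 (adjusted p = 0.00667), from 1190 ± 240 CPM to 768 ± 150 CPM. Sox9, a transcription factor gene of the same cells, rose by 0.62 ± 0.15 (adjusted p = 0.0084), and the Sertoli-expressed homeobox gene Rhox8 changed by −1.27 ± 0.15. In all, 5 of 24 Sertoli cell genes rose and 2 fell (12 and 2 adjusted over the list alone; adjusted p = 0.689 with an estimated correlation). The Leydig cell genes Star (0.11 ± 0.14, adjusted p = 0.809), Cyp11a1 (0.01 ± 0.12, adjusted p = 0.987), Cyp17a1 (−0.03 ± 0.21, adjusted p = 0.974) and Insl3 (0.05 ± 0.14, adjusted p = 0.92) did not pass the test. The germ cell genes Ddx4 (−0.16 ± 0.16), Pou5f1 (−0.22 ± 0.18) and Nanos2 (−0.80 ± 0.43), the meiotic cohesin gene Rec8 (0.20 ± 0.23), Dhh (0.31 ± 0.10), Foxl2 (0.72 ± 0.24), Acta2 (−0.17 ± 0.09), Fos (−0.33 ± 0.21) and Mki67 (−0.04 ± 0.06) did not pass either. Dhh did pass with a block on the first number in the titles, over all libraries or within each range. The immediate early gene Egr1 had −0.60 ± 0.16 (adjusted p = 0.0229), a call lost without any one of MEHP replicates 1, 3 and 5 and vehicle replicates 3 and 11, at adjusted p values up to 0.0761.

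A further 6 lists passed only at the preset correlation with MEHP. The first was the Sertoli cell list. Of 14 endothelial cell genes, 4 were higher (7 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation). The calls of Esam, Pecam1 and Kdr were lost in 10, 14 and 17 of 30 fits without 1 library, at adjusted p values up to 0.149. MEHP replicate 1 was among those libraries for each of these genes. Of 18 ATF4 and unfolded protein response genes, 2 were higher (4 adjusted over the list alone; adjusted p = 0.474 with an estimated correlation). Of 12 NRF2 target genes, 3 were higher (3 adjusted over the list alone; adjusted p = 0.236 with an estimated correlation), and the calls of Osgin1 and Hmox1 were both lost without any one of MEHP replicates 2, 3 and 6 and vehicle replicates 6 and 10, at adjusted p values up to 0.106. Of 15 anterior Hox genes, 0 were called (2 higher adjusted over the list alone), and of 12 pluripotency genes 0 were called (0 adjusted over the list alone). Both had an adjusted p = 0.689 with an estimated correlation. Chac1 (0.94 ± 0.20), Trib3 (0.52 ± 0.11), Srxn1 (0.42 ± 0.08) and Cldn5 (0.86 ± 0.22) were the members with the smallest p in their lists, and the call of Cldn5 was lost with only the MEHP and upper-range vehicle libraries fitted. In all, MEHP raised 556 genes and lowered 356 (edgeR quasi-likelihood test), 103 of them by at least 2-fold. Fitting only the MEHP and upper-range vehicle libraries called 439 genes, 436 of them among the 912, while leaving out the range term called 2229.

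ATRA induced retinoid targets and meiotic genes. Cyp26a1 (ENSMUSG00000024987, chromosome 19, 37697808 to 37701528) rose by 6.10 ± 0.31 in log2 (adjusted p = 2.32e-15, edgeR), from 0.235 ± 0.19 CPM in lower-range vehicle libraries (n = 9) to 17.2 ± 7.3 CPM (n = 5). Stra8 rose by 5.03 ± 0.32, from 4.31 ± 2.7 CPM to 142 ± 55 CPM. Rarb rose by 3.85 ± 0.16 and Dhrs3 by 2.59 ± 0.06. Of 25 retinoic acid response genes, 19 rose and 3 fell (19 and 3 adjusted over the list alone; adjusted p = 2.79e-11 with an estimated correlation). Of 25 tested meiosis genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone; adjusted p = 0.0487 with an estimated correlation, and up to 0.0593 in the 11 of 30 fits without 1 library that did not pass), among them Rec8 (2.08 ± 0.20), the meiotic cohesin gene Smc1b (1.89 ± 0.10) and the recombinase gene Dmc1 (0.78 ± 0.10). Stra8 is a member of both lists. Of 15 anterior Hox genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 0.0383 with an estimated correlation, 0.0502 without MEHP replicate 4), with Hoxb1 at 4.01 ± 0.38, Hoxa4 at 2.34 ± 0.32 and Hoxb4 at 2.2 ± 0.19. In lower-range vehicle libraries, Hoxb1 stood at 0.125 ± 0.11 CPM and Hoxa4 at 0.457 ± 0.19 CPM, so their folds start from few reads.

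**Figure D1:**
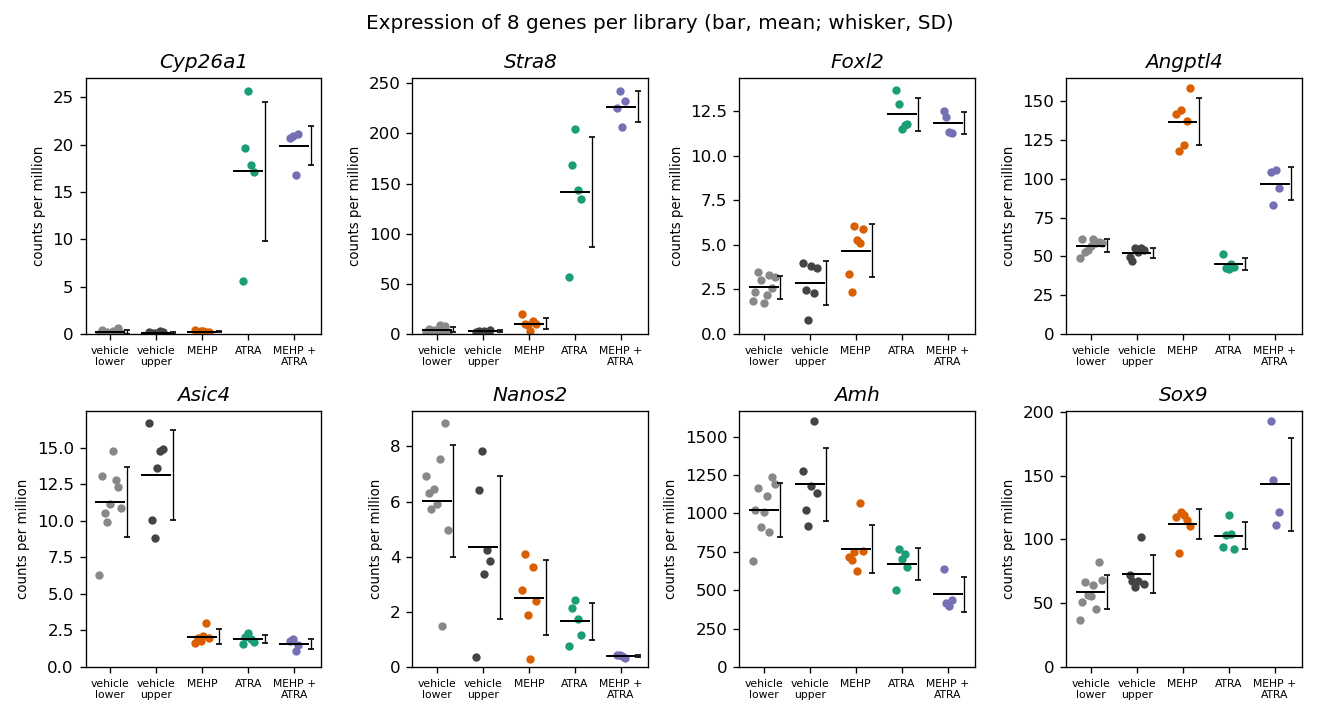
Expression of 8 genes in CPM, with 1 point per library for vehicle in the lower range (n = 9), vehicle in the upper range (n = 6), MEHP (n = 6), ATRA (n = 5) and MEHP + ATRA (n = 4). Horizontal bars are means and whiskers are ± SD. Cyp26a1, Stra8 and Foxl2 were higher in every ATRA and MEHP + ATRA library than in vehicle, and Asic4 was low in all 3 treatments.

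Among called genes with a mean log2 CPM of at least 1, other large rises with ATRA were Tnfsf13b, which encodes a B cell activating cytokine (4.73 ± 0.18), Lpar3 (4.09 ± 0.20), the caudal homeobox gene Cdx1 (3.90 ± 0.31), the cytokine gene Il33 (3.81 ± 0.33) and Ecm1 (3.31 ± 0.09). In lower-range vehicle libraries, Tnfsf13b, Lpar3 and Cdx1 had low mean levels of 0.515, 0.528 and 0.383 CPM. Large falls were those of Miox (−2.61 ± 0.29), Asic4 (−2.54 ± 0.19), Slc13a2 (−2.38 ± 0.17), Lamp5 (−2.25 ± 0.26), Pcdh8 (−2.15 ± 0.24), Slc13a2os (−2.06 ± 0.28) and Hsd17b1, which encodes an estrogenic 17β-hydroxysteroid dehydrogenase (−2.04 ± 0.15). Asic4 stood at 1.92 ± 0.28 CPM with ATRA (n = 5) and 11.3 ± 2.4 CPM in lower-range vehicle libraries (n = 9).

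Somatic cell markers moved in both directions with ATRA. Of 16 ovarian somatic cell genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 0.0579 with an estimated correlation). Foxl2, a transcription factor gene of granulosa cells (ENSMUSG00000050397, chromosome 9, 98955607 to 98956847), rose by 2.23 ± 0.21, from 2.63 ± 0.65 CPM to 12.3 ± 0.94 CPM, Wnt4 rose by 1.46 ± 0.08 and Runx1 by 1.13 ± 0.15. Of 24 Sertoli cell genes, 12 rose and 4 fell (13 and 6 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). Nr0b1 (2.23 ± 0.12), Cldn11 (1.66 ± 0.16), Cst9 (1.18 ± 0.11), Aard (1.18 ± 0.12) and Sox9 (0.81 ± 0.14) rose, whereas Amh fell by 0.61 ± 0.14 in log2 (adjusted p = 0.0022). Dhh, the Hedgehog ligand gene of Sertoli cells, rose by 0.38 ± 0.10. Of 16 interstitial progenitor genes, 2 rose and 7 fell (2 and 8 adjusted over the list alone; adjusted p = 0.334 with an estimated correlation), with Col3a1 at −0.54 ± 0.06, Pdgfra at −0.49 ± 0.06, Lhx9 at −0.66 ± 0.08 and Dcn in the other direction at 1.04 ± 0.12. Of 12 peritubular myoid and smooth muscle genes, 0 rose and 4 fell (0 and 6 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), including Tpm1 (−0.54 ± 0.08), Myl9 (−0.33 ± 0.07), Tpm2 (−0.24 ± 0.05) and Tagln (−0.99 ± 0.22). Acta2 had 0.17 ± 0.09 and did not pass.

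Immediate early genes were lower with ATRA, 11 of 19 with 0 higher (12 and 0 adjusted over the list alone; adjusted p = 0.0897 with an estimated correlation). Btg2 changed by −0.73 ± 0.08, Ier2 by −0.57 ± 0.07, Egr1 by −1.0 ± 0.16 and Egr3 by −1.62 ± 0.34, while Fos had −0.30 ± 0.20 (adjusted p = 0.376). Of 23 proliferation genes, 8 fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 0.61 with an estimated correlation), among them Aurkb (−0.36 ± 0.06), Mki67 (−0.32 ± 0.06), Birc5 (−0.26 ± 0.06) and Tpx2 (−0.24 ± 0.06). Of 25 cholesterol biosynthesis genes, 4 rose (4 adjusted over the list alone; adjusted p = 0.79 with an estimated correlation), among them Idi1 (0.35 ± 0.08), and the calls of Mvd and Sc5d were lost without ATRA replicate 2 (adjusted p = 0.077 and 0.0816). Nanos2, a gene of male germ cell differentiation, fell by 1.86 ± 0.44 in log2 (adjusted p = 0.00248), from 6.02 ± 2.0 CPM to 1.65 ± 0.68 CPM. Ddx4 (0.13 ± 0.15) and Pou5f1 (0.00 ± 0.17) did not pass. Angptl4 had −0.34 ± 0.07 (adjusted p = 0.000714), and Pdk4 (0.17 ± 0.16), Hmgcs1 (0.13 ± 0.07), Cyp11a1 (−0.04 ± 0.11), Cyp17a1 (0.18 ± 0.20) and Insl3 (0.02 ± 0.14) did not pass. Star had 0.38 ± 0.13 (adjusted p = 0.0428), a call lost without any one of ATRA replicates 1 to 5, vehicle replicates 2, 5, 8, 12 and 15 and MEHP + ATRA replicates 3 and 4, at adjusted p values up to 0.11. ATRA raised 1750 genes and lowered 1744 (edgeR quasi-likelihood test), 629 of them by at least 2-fold. limma-voom with sample weights called 5527.

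**Figure D2:**
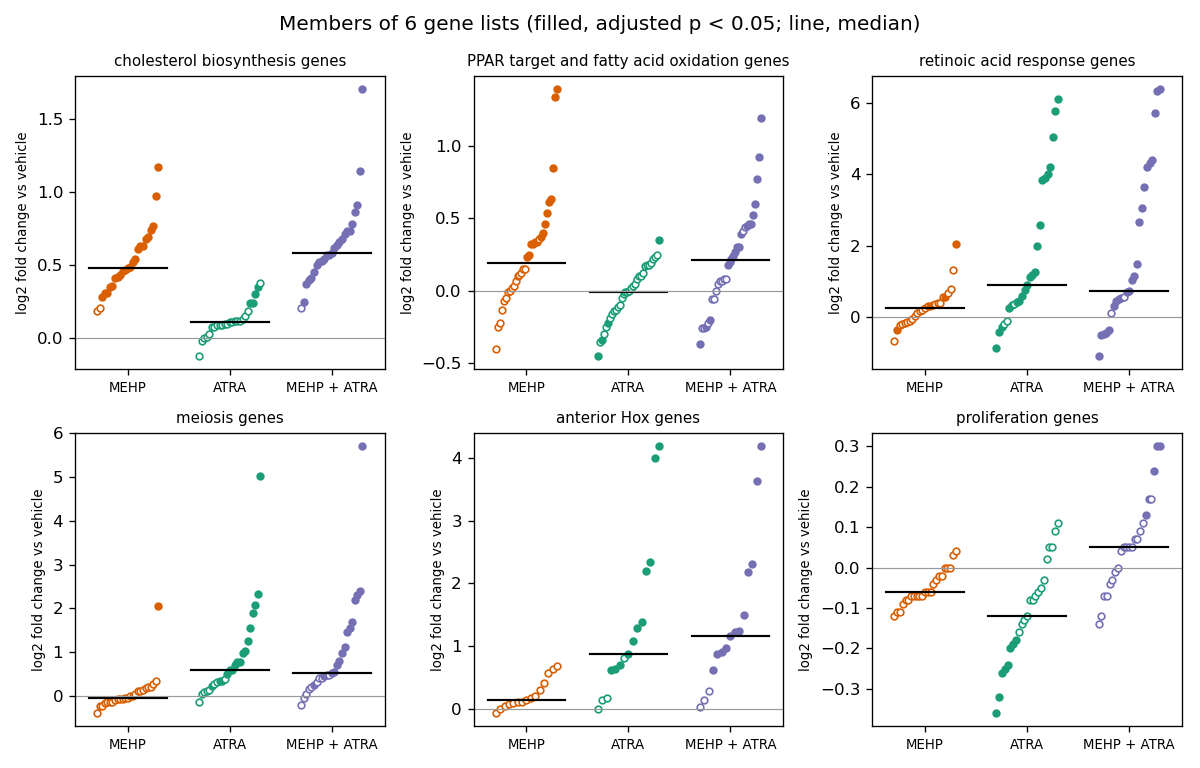
Log2 fold changes against vehicle of the tested members of 6 gene lists, with 1 point per gene in rising order for MEHP, ATRA and MEHP + ATRA. Filled points passed the test (adjusted p under 0.05), and horizontal lines are medians. The cholesterol biosynthesis list has its median at 0.48 with MEHP, 0.11 with ATRA and 0.58 with both.

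MEHP + ATRA raised both cholesterol biosynthesis and retinoic acid response genes. Of 25 cholesterol biosynthesis genes, 24 rose and 0 fell (25 and 0 adjusted over the list alone; adjusted p = 0.033 with an estimated correlation, 0.0518 without MEHP + ATRA replicate 3), with Mvd at 1.14 ± 0.08, Sc5d at 0.91 ± 0.08, Nsdhl at 0.78 ± 0.09, Pmvk at 0.73 ± 0.08 and Hmgcs1 at 0.50 ± 0.08. Of 25 retinoic acid response genes, 18 rose and 5 fell (19 and 5 adjusted over the list alone; adjusted p = 4.37e-10 with an estimated correlation). Cyp26a1 rose by 6.31 ± 0.32 to 19.9 ± 2.1 CPM (n = 4), Stra8 by 5.70 ± 0.33 to 227 ± 15 CPM, Rarb by 4.30 ± 0.17 and Dhrs3 by 3.06 ± 0.07. Tnfsf13b (5.29 ± 0.19), Cdx1 (4.40 ± 0.31), Il33 (3.97 ± 0.34), Lpar3 (3.87 ± 0.21) and the granulocyte transcription factor gene Cebpe (3.83 ± 0.24) completed the largest rises. The largest falls were deeper than with either compound alone in point estimate: Lamp5 −5.47 ± 0.43, Miox −5.29 ± 0.43, Slc13a2 −4.69 ± 0.24, Hsd17b1 −3.98 ± 0.20, Nanos2 −3.92 ± 0.60, Grm7 −3.89 ± 0.35, Mug-ps1 −3.72 ± 0.37 and Slc13a2os −3.64 ± 0.36. In the 4 co-exposed libraries, Lamp5 was at 0 to 0.122 CPM and Miox at 0.045 to 0.129 CPM. Grm7 was at 0.14 to 0.244 CPM and Slc13a2os at 0 to 0.407 CPM in the same libraries, so these folds rest on few reads. Mug-ps1 is a pseudogene that can share reads with its parent family. Reads of Acot1 can likewise be shared with its paralogs, and those of Hox genes with antisense transcripts. Nanos2 stood at 0.395 ± 0.048 CPM (n = 4).

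The other lists called under MEHP + ATRA passed only at the preset correlation. Of 25 meiosis genes, 16 were higher and 0 lower (18 and 0 adjusted over the list alone), and of 15 anterior Hox genes 12 were higher (12 adjusted over the list alone), both with an adjusted p = 0.0927 with an estimated correlation. Of 32 PPAR target and fatty acid oxidation genes, 16 were higher and 3 lower (16 and 3 adjusted over the list alone). Of 18 ATF4 and unfolded protein response genes, 12 were higher and 1 lower (13 and 1 adjusted over the list alone). Both had an adjusted p = 0.133 with an estimated correlation. Of 12 NRF2 target genes, 7 were higher (7 adjusted over the list alone), and of 16 ovarian somatic cell genes 6 were higher (6 adjusted over the list alone), both with an adjusted p = 0.13 with an estimated correlation. Of 24 Sertoli cell genes, 13 were higher and 3 lower (13 and 5 adjusted over the list alone; adjusted p = 0.271 with an estimated correlation). Of 19 immediate early genes, 1 was higher and 12 lower (1 and 12 adjusted over the list alone; adjusted p = 0.201 with an estimated correlation). Of 16 interstitial progenitor genes, 2 were higher and 7 lower (2 and 8 adjusted over the list alone; adjusted p = 0.186 with an estimated correlation). Of 12 peritubular myoid and smooth muscle genes, 6 were lower (6 adjusted over the list alone; adjusted p = 0.201 with an estimated correlation).

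Within these lists, Smc1b (2.18 ± 0.10), Rec8 (2.39 ± 0.20) and Dmc1 (0.99 ± 0.11) rose among the meiosis genes and Hoxb1 (3.63 ± 0.41), Hoxa4 (2.31 ± 0.34) and Hoxb4 (2.18 ± 0.20) among the Hox genes. The stress response genes Chac1 (1.57 ± 0.19), Trib3 (1.16 ± 0.11), Asns (1.08 ± 0.12), Psat1 (1.07 ± 0.11), Osgin1 (1.01 ± 0.16), Srxn1 (0.61 ± 0.08), Gclc (0.42 ± 0.08) and Gclm (0.36 ± 0.06) rose. Acot1 (0.92 ± 0.08), Angptl4 (0.77 ± 0.07) and Cpt1a (0.60 ± 0.07) rose among the PPAR targets. Pdk4 had 0.52 ± 0.16 (adjusted p = 0.0165), lost without MEHP + ATRA replicate 3 (adjusted p = 0.0995). Foxl2 (2.17 ± 0.22), Wnt4 (1.72 ± 0.08), Runx1 (1.64 ± 0.16) and Lgr5 (0.83 ± 0.14) rose among the ovarian genes and Nr0b1 (2.54 ± 0.12), Cldn11 (1.76 ± 0.17), Fgf9 (1.40 ± 0.15), Sox9 (1.28 ± 0.14), Cst9 (1.27 ± 0.12) and Dhh (0.51 ± 0.10) among the Sertoli genes. Amh changed by −1.11 ± 0.16, from 1020 ± 180 CPM to 473 ± 110 CPM. Egr3 (−2.62 ± 0.42), Egr1 (−1.12 ± 0.18), Btg2 (−0.88 ± 0.08) and Ier2 (−0.56 ± 0.08) fell. In the somatic lists, the falls included Lhx9 (−0.98 ± 0.09), Col3a1 (−0.76 ± 0.07), Pdgfra (−0.60 ± 0.06), Myh11 (−0.64 ± 0.08), Tpm1 (−0.59 ± 0.09), Myl9 (−0.44 ± 0.07) and Tpm2 (−0.25 ± 0.06). Fos had −0.62 ± 0.22 (adjusted p = 0.0335), lost without any one of MEHP + ATRA replicates 1 to 4 and vehicle replicate 5, at adjusted p values from 0.05 to 0.117. Star rose by 0.81 ± 0.14, and Cyp11a1 (0.09 ± 0.12), Cyp17a1 (0.46 ± 0.21), Insl3 (−0.10 ± 0.15), Ddx4 (0.02 ± 0.17), Pou5f1 (−0.25 ± 0.19), Acta2 (0.14 ± 0.10) and Mki67 (−0.04 ± 0.07) did not pass. MEHP + ATRA raised 2756 genes and lowered 2839 (edgeR quasi-likelihood test), 1248 of them by at least 2-fold.

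Adding MEHP to ATRA changed 579 genes, 313 higher and 266 lower, 95 of them by at least 2-fold (MEHP + ATRA against ATRA, edgeR). Cholesterol biosynthesis genes rose in 22 of 25 cases with 0 lower (25 and 0 adjusted over the list alone; adjusted p = 0.000251 with an estimated correlation), led by Mvd (0.90 ± 0.09), Pmvk (0.75 ± 0.09), Sc5d (0.67 ± 0.09) and Nsdhl (0.67 ± 0.10). PPAR target and fatty acid oxidation genes rose in 8 of 32 (13 adjusted over the list alone; adjusted p = 0.000733), with Angptl4 at 1.10 ± 0.08, Cpt1a at 0.65 ± 0.08 and Acadl at 0.43 ± 0.07. ATF4 and unfolded protein response genes rose in 9 of 18 with 0 lower (11 and 1 adjusted over the list alone; adjusted p = 0.0128), with Chac1 at 1.26 ± 0.22, Asns at 0.72 ± 0.14, Trib3 at 0.66 ± 0.12 and Atf4 at 0.50 ± 0.09. The retinoid target Dhrs3 (0.46 ± 0.07) was higher with both compounds than with ATRA, and the retinoic acid response list had an adjusted p of 0.0575 with an estimated correlation (3 of 25 higher, 5 higher and 1 lower adjusted over the list alone). The proliferation list was higher (3 of 23 genes, 16 adjusted over the list alone; adjusted p = 0.0333), with Tpx2 at 0.29 ± 0.07, Ccnb2 at 0.30 ± 0.08 and Mki67 at 0.29 ± 0.07. The list did not pass without any one of ATRA replicates 1 and 3 and MEHP + ATRA replicates 2 and 3 (up to 0.0678). Each of the 3 gene calls was lost without MEHP + ATRA replicate 1 or 4. Those of Tpx2 and Mki67 were also lost without MEHP + ATRA replicate 3, and those of Ccnb2 and Mki67 without ATRA replicate 1, at adjusted p values up to 0.111.

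Among the lists held with the estimated correlation, male germ cell differentiation and NRF2 targets had no member called over all genes in this comparison. The male germ cell differentiation list was lower (0 of 11 genes, 1 adjusted over the list alone; adjusted p = 0.025), with Nanos2 at −2.06 ± 0.65 (adjusted p = 0.0862), Morc1 at −0.69 ± 0.30, Nodal at −1.07 ± 0.48 and Lefty2 at −0.58 ± 0.25. Without ATRA replicate 3, Nodal had −0.44 and Lefty2 −0.33, and the list had an adjusted p of 0.0334. Genes of the male germ cell differentiation list had a median correlation of 0.74 with the axis of germ cell genes described below. An unequal position of the ATRA and MEHP + ATRA libraries on that axis was not told apart from an effect of MEHP. The NRF2 target list was higher (0 of 12 genes, 3 adjusted over the list alone; adjusted p = 0.0296), with Osgin1 at 0.62 ± 0.18 and Txnrd1 at 0.20 ± 0.06, and did not pass without MEHP + ATRA replicate 1 or 3 (0.0554 and 0.0508). Pluripotency (1 of 12 lower, 3 adjusted over the list alone; adjusted p = 0.588), interstitial progenitor (1 of 16 lower, 4 adjusted over the list alone; adjusted p = 0.406) and endothelial cell genes (0 of 14, 0 adjusted over the list alone; adjusted p = 0.588) passed only at the preset correlation. Among called genes with a mean log2 CPM of at least 1, Cox6a2 (1.51 ± 0.25), Slc25a34 (1.44 ± 0.18), Atp8b1 (1.28 ± 0.22) and Scin (1.28 ± 0.22) were among those that rose most. By the same limit, Lamp5 (−3.22 ± 0.54), Miox (−2.68 ± 0.53), Slc13a2 (−2.31 ± 0.27), Grm7 (−2.07 ± 0.40) and Hsd17b1 (−1.94 ± 0.21) fell most. Without MEHP + ATRA replicate 1 the count was 340, and limma-voom with sample weights called 1656. A block on the first number in the titles gave 1371, and that block within each range 623. Adding ATRA to MEHP (MEHP + ATRA against MEHP) changed 1601 genes, 784 higher and 817 lower. Of 25 retinoic acid response genes, 14 were higher and 1 lower (16 and 3 adjusted over the list alone; adjusted p = 3.42e-10 with an estimated correlation). Of 25 meiosis genes, 10 were higher (13 adjusted over the list alone; adjusted p = 0.0452 with an estimated correlation). Those groups lie in different ranges, and the count was 3181 without the range term and 2413 with the maturity score as a covariate.

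In the fit without a block on title numbers, the effect of MEHP differed with ATRA present for 6 genes. With a block on the first number in the titles, only Asic4, Cytip and Spata21 kept the call. With that block within each range, only Asic4 and Cytip did. Asic4 fell by 2.66 on the log2 scale with MEHP alone and stood at −0.30 ± 0.24 when MEHP was added to ATRA, an interaction of 2.35 ± 0.30 (adjusted p = 0.000184, edgeR). ATRA alone had already brought Asic4 to 1.92 ± 0.28 CPM, against 2.08 ± 0.49 CPM with MEHP alone and 1.57 ± 0.36 CPM with both. The interaction therefore does not show that ATRA blocked the effect of MEHP on this gene. Plekhd1 had an interaction of 1.06 ± 0.19 (adjusted p = 0.0245), with −0.86 ± 0.13 for MEHP alone and 0.21 ± 0.15 with ATRA. Its level was already 5.17 ± 0.79 CPM with ATRA alone, against 5.32 ± 0.76 CPM with MEHP alone and 5.97 ± 1.2 CPM with both. Vehicle libraries held 9.64 ± 1.7 CPM in the upper range and 7.12 ± 0.85 CPM in the lower range. For Plekhd1 too, the interaction does not show that ATRA blocked the effect of MEHP. Cytip, which encodes a cytohesin-interacting protein, had −1.37 ± 0.24 (adjusted p = 0.0121), with 1.69 ± 0.17 alone and 0.32 ± 0.17 with ATRA. Its level was already 12.3 ± 1.1 CPM with ATRA alone and was 15.4 ± 0.9 CPM with both, against 2.18 ± 0.34 CPM in lower-range vehicle libraries. Tdrp, a gene of testis development, had −0.75 ± 0.12 (adjusted p = 0.00566), with 0.86 ± 0.08 alone and 0.11 ± 0.09 with ATRA. Spata21, a spermatogenesis-associated gene, went further down with ATRA present, with −0.65 ± 0.11 alone and −1.86 ± 0.16 with ATRA, an interaction of −1.21 ± 0.20 (adjusted p = 0.00566). Lamp5 had −3.10 ± 0.59 (adjusted p = 0.037), with −0.11 ± 0.21 alone and −3.22 ± 0.54 with ATRA. Leaving out 1 library gave interaction values of −4.34 to −2.72 for Lamp5, which was at 0 to 0.122 CPM with both compounds, a level of few reads. The call of Lamp5 was lost without any one of MEHP replicates 5 and 6, ATRA replicates 1, 2, 4 and 5, MEHP + ATRA replicates 1, 2 and 3 and vehicle replicates 3, 4, 6, 7, 10, 12, 13 and 14 (adjusted p up to 0.176). That of Plekhd1 was lost without any one of MEHP replicate 6, ATRA replicates 2 and 4, MEHP + ATRA replicate 2 and vehicle replicates 10 and 14 (up to 0.11), and that of Cytip without MEHP + ATRA replicate 2 (0.0512), where 3 genes were called in all.

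**Figure D3:**
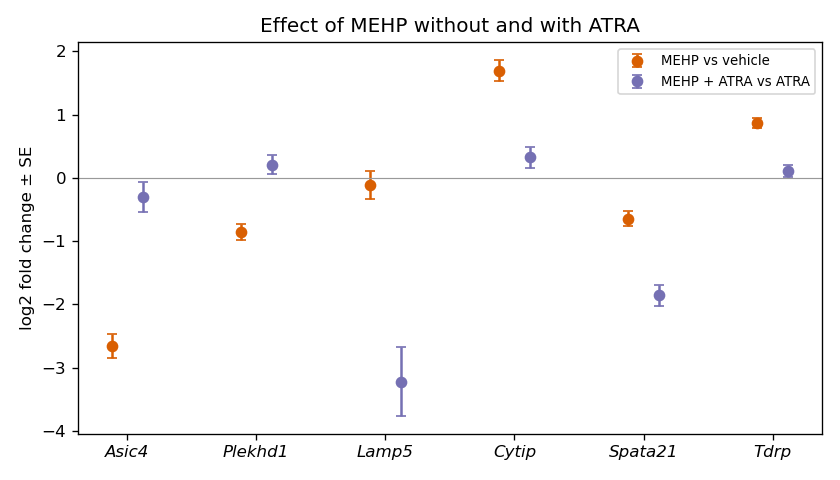
Log2 fold change ± SE of the effect of MEHP against vehicle (n = 6 and 6) and of MEHP + ATRA against ATRA (n = 4 and 5) for the 6 genes whose interaction passed the test in the fit without a block on title numbers. Asic4 had −2.66 without ATRA and −0.30 with it, and Spata21 had −0.65 and −1.86. With ATRA alone against vehicle, Asic4 had −2.54.

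Of the gene lists, the interaction of the proliferation genes was above 0 (0 of 23 genes called alone, 15 higher adjusted over the list alone; adjusted p = 0.00552 with an estimated correlation), with a median of 0.24. Single values were Aurkb at 0.32 ± 0.09, Mki67 at 0.32 ± 0.10, Tpx2 at 0.31 ± 0.09 and Bub1b at 0.21 ± 0.06. The mean log2 CPM of the list was 7.08 ± 0.04 in lower-range vehicle (SD, n = 9), 7.09 ± 0.07 in upper-range vehicle (n = 6), 7.04 ± 0.09 with MEHP (n = 6), 6.97 ± 0.06 with ATRA (n = 5) and 7.14 ± 0.02 with MEHP + ATRA (n = 4). Another 4 lists passed only at the preset correlation. Of 16 interstitial progenitor genes, 0 were called (1 lower adjusted over the list alone; adjusted p = 0.316 with an estimated correlation), and of 7 Hedgehog response genes 0 (1 lower adjusted over the list alone; adjusted p = 0.274). Of 15 macrophage genes, 0 were called (0 adjusted over the list alone; adjusted p = 0.343), and of 18 ATF4 and unfolded protein response genes 0 (0 adjusted over the list alone; adjusted p = 0.242). DESeq2 called 12 genes for the interaction with the same design, and 827 genes had an unadjusted p under 0.05.

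The effects of MEHP and ATRA overlapped. Of the genes called with MEHP, 312 rose with both compounds where independent calls would share 50.4, 245 fell with both where 32.1 would, and 16 went in opposite directions where 82.4 would. Across all genes tested, the log2 fold changes of the 2 comparisons, which use different vehicle libraries, had a correlation of 0.37 (genes are not independent replicates). The MEHP effect without ATRA and with ATRA, also from separate libraries, shared 198 rises (9.0 by independent calls) and 114 falls (4.9) with 0 in opposite directions, at a correlation of 0.50. ATRA and MEHP + ATRA were compared with the same 9 vehicle libraries and shared 1559 rises (249.6 by independent calls) and 1440 falls (256.2). Over 15867 genes at or above 1 CPM in these vehicles, their correlation was 0.87 with a covariance of 0.146. Simulated unchanged groups against the same vehicles gave 0.32 and 0.007, and with the vehicles split (4 for ATRA, 5 for MEHP + ATRA) the correlation was 0.83 and the covariance 0.142.

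Vehicle libraries of the upper range differed from those of the lower range in 72 genes, 49 higher and 23 lower (edgeR). Cbln4 (0.79 ± 0.18), Sel1l3 (0.65 ± 0.15) and Cage1 (0.56 ± 0.10) had the largest rises and Enpp3 (−0.77 ± 0.14), Hrc (−0.65 ± 0.15) and Ccdc170 (−0.61 ± 0.13) the largest falls. The calls of Cbln4 and Sel1l3 were lost without vehicle replicate 11 (adjusted p = 0.189 and 0.164), among 22 and 15 libraries that ended them. That of Enpp3 was lost without vehicle replicate 14 (0.055), that of Ccdc170 without any one of vehicle replicates 1, 2, 3 and 14 (up to 0.0672). That of Hrc was lost without any one of vehicle replicates 1, 2, 3, 5, 7, 8, 11, 14 and 15 (up to 0.142). Of 25 cholesterol biosynthesis genes, 1 was higher in the upper range (14 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation), and none of the 9 lists called at the preset correlation held with an estimated one. With only the 15 vehicle libraries fitted, 4 genes were called, and leaving out 1 library gave 10 (without vehicle replicate 14) to 169 (without vehicle replicate 4). DESeq2 called 338, and 445 were called with the maturity score as a covariate. Libraries of the same group also spread along a common axis of germ cell genes. Its first component held 47.3% of the variance of the 2000 most variable genes within groups, against 7.1% for the second, with Dnmt3l, Spocd1 and Sohlh1 at one end and Sox2, Nanog and Dppa3 at the other. The male germ cell differentiation, meiosis and pluripotency lists had median correlations of 0.74, 0.56 and −0.46 with this axis. Lists of other kinds followed it too, with 0.52 for hypoxia and glycolysis, −0.48 for cholesterol biosynthesis and −0.46 for erythroid genes. Others had values near 0, such as macrophage (0.03) and ovarian somatic cell genes (−0.05). Mean maturity scores, from genes called in no treatment against vehicle and not between the ranges, were −0.29 ± 1.32 with MEHP (n = 6), 0.40 ± 0.82 with ATRA (n = 5), −0.08 ± 0.28 with MEHP + ATRA (n = 4), 0.01 ± 0.87 in lower-range vehicle (n = 9) and −0.02 ± 1.41 in upper-range vehicle (n = 6). That choice of genes draws the group means together, so equal maturity of the groups cannot be read from them.

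**Figure D4:**
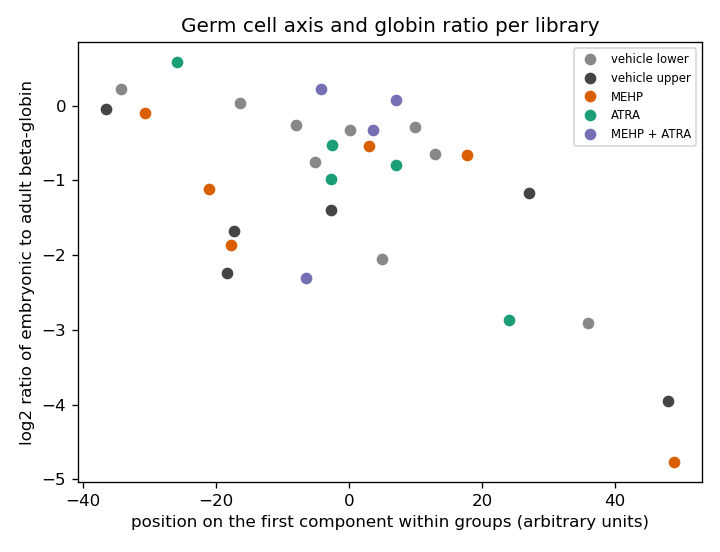
Position of each of the 30 libraries on the first component within groups (arbitrary units, x axis) against its log2 ratio of embryonic to adult beta-globin counts (y axis), coloured by group. Vehicle 3 and MEHP 4 lie at 47.9 and 48.8 on the axis with the lowest ratios, −3.95 and −4.77. The axis shown was not rebuilt without erythroid genes, unlike the axis tested in the text. The embryonic beta-globin gene Hbb-y had a correlation of −0.72 with the axis shown, so the plotted relation is in part built in.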

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

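The tests of the germ cell axis below were chosen after the axis was seen, and those of the proliferation genes were written before they were run, except the test of the title ranges, while the maturity score they use was chosen after the data were seen. Among 30 genes in 150 gene and group pairs, 12 libraries stood far from the others of their group, and chance picks out about 1 in 20 groups. Nanos2 was at 0.275 CPM in MEHP replicate 4 (others 1.91 to 4.10), at 0.369 CPM in vehicle replicate 3 (others of the upper range 3.37 to 7.85) and at 1.48 CPM in vehicle replicate 12 (others of the lower range 4.99 to 8.84). Cyp17a1 was at 59.9 CPM in MEHP replicate 4 (others 119 to 177), Amh at 1070 CPM in MEHP replicate 5 (others 623 to 758) and Sox9 at 89.5 CPM in MEHP replicate 2 (others 110 to 121). Cyp26a1 was at 5.58 CPM in ATRA replicate 1 (others 17.2 to 25.7) and at 16.8 CPM in MEHP + ATRA replicate 3 (others 20.8 to 21.1). Sox9 was at 102 CPM in vehicle replicate 11 (others of the upper range 62.4 to 72.3), Foxl2 at 0.796 CPM in vehicle replicate 6 (others 2.33 to 4.0) and Asic4 at 6.31 CPM in vehicle replicate 1 (others of the lower range 9.91 to 14.8). Plekhd1 was at 7.73 CPM in MEHP + ATRA replicate 2 (others 5.36 to 5.42).

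The 3 libraries with outlying Nanos2 lay farthest toward the Dnmt3l end of the germ cell axis, at 48.8, 47.9 and 36. Library size (Spearman's rho −0.24 within groups) and attached mesonephros (median correlation of its genes with the axis −0.09) were argued against as the source of the axis. Embryos of different developmental age may be the source, since the ratio of embryonic to adult beta-globin fell along the axis rebuilt without erythroid genes (r = −0.70, permutation p = 1e-05, the smallest the permutations can give; rho = −0.46, p = 0.01; n = 30; lower range r = −0.69 and rho = −0.58, upper range r = −0.71 and rho = −0.51). Without MEHP replicate 4 and vehicle replicate 3, r was −0.52 (permutation p = 0.0041) and rho −0.34 (p = 0.078), so the rank relation rests in part on those libraries. A source shared by libraries with the same first number in their titles stays open beside age, with 52.8% of the axis variance between first numbers (permutation p = 0.0074) and all 8 libraries of one first number below their group means, and what the numbers stand for is not given in the sources used here.

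In the fit without a block on title numbers, a difference between the MEHP effect with and without ATRA passed the test for Asic4 (2.35), Plekhd1 (1.06), Lamp5 (−3.10), Cytip (−1.37), Spata21 (−1.21) and Tdrp (−0.75), as log2 values. Of these, Asic4, Cytip and Spata21 passed with a block on the first number, and Asic4 and Cytip with that block within each range. At the preset correlation the difference also passed for interstitial progenitor (median −0.13), Hedgehog response (−0.26), macrophage (−0.22), proliferation (0.24) and ATF4 and unfolded protein response genes (0.19), and of these lists only the proliferation genes held with an estimated correlation.

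All 23 proliferation genes had an interaction above 0. The median interaction was 0.241 with the maturity score as a covariate and 0.236 without it. The genes of the score were chosen for no difference between groups, so it cannot decide on unequal germ cell maturity. Scaling between libraries was argued against by a median of 0.247 with DESeq2 size factors. The spread of the list's mean between libraries was argued against by a permutation test of its interaction of 0.23 (p = 0.0047). A level difference between the title ranges was argued against, since the median was 0.235 without the range term, but an effect of MEHP that itself differs between ranges was not tested, since no ATRA library lay in the upper range.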

How the results depend on the processing

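The maturity score, a block within each range and leaving out 1 library with an estimated correlation were the only alternatives chosen after the data were seen. Of 12091 values of named genes under the alternatives, 11658 kept their direction and side of the threshold, 278 lost the call, 155 gained it and 0 reversed, and 177 of 211 called values passed in every setting run. Without the range term, MEHP called 2229 genes (912 with it), MEHP + ATRA against MEHP 3181 (1601) and the interaction 10 (6), and DESeq2 without it called 2526, 3401 and 59. Only the libraries of the comparison gave 439 genes for MEHP and 4 for the range. The limma-voom fit with sample weights called 5527 for ATRA (3494), 1656 for MEHP + ATRA against ATRA (579), 10 for the interaction and 136 for the range (72), and DESeq2 called 12 for the interaction and 338 for the range. Without a filter, 19 were called for the range. With the maturity score, 2413 were called for MEHP + ATRA against MEHP and 445 for the range. The cause of these differences was not tested, except that fitting only the libraries of a comparison uses fewer libraries.

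With a replicate block on the first number, MEHP + ATRA against ATRA called 1371 genes, the interaction 3 (Asic4, Cytip and Spata21) and the range 42. The 75 pairs of libraries with the same first number had a mean residual correlation of 0.104 and the 360 other pairs −0.061, and 35 of the 75 were over 0.1. Each of the 9 first numbers within a range held as many treated as vehicle libraries. The 27 treated and vehicle pairs they form had a mean correlation of 0.199, against −0.058 for the 90 pairs of one range with different first numbers. Of the 27, 17 were over 0.1, the 3 single pairs among them from 0.111 to 0.542, but 1 first number had no pair over 0.078, and 12 of 30 libraries correlated best with one of their own number and range. Where a first number held more than 1 treated library, these pairs also join libraries that a pairing would keep apart. Pairs at or under 0.1 therefore do not argue against a pairing. The matched numbers of libraries and the higher mean correlation leave it possible, but the labels do not say what the numbers stand for. A pairing was neither used nor excluded, and the main tests take no account of one. A replicate block on the first number within each range called 1227 genes for MEHP, 3848 for ATRA, 6021 for MEHP + ATRA, 623 for MEHP + ATRA against ATRA, 1940 for MEHP + ATRA against MEHP and 2 for the interaction (Asic4 and Cytip). Dhh passed with MEHP under both blocks. Lists called fell with an estimated correlation from 9 to 3 (MEHP), 10 to 3 (ATRA), 12 to 2 (MEHP + ATRA), 10 to 6 (MEHP + ATRA against ATRA) and 5 to 1 (interaction), and the interaction called 10 lists without the range term and 8 with the maturity score.

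Leaving out 1 library gave 668 to 1151 genes for MEHP, 2914 to 3763 for ATRA, 4613 to 5980 for MEHP + ATRA and 1307 to 1724 for MEHP + ATRA against MEHP. It gave 340 (without MEHP + ATRA replicate 1) to 689 for MEHP + ATRA against ATRA, and 3 (without MEHP + ATRA replicate 2) to 8 for the interaction. For the range it gave 10 (without vehicle replicate 14) to 169 (without vehicle replicate 4), with 28, 17, 34, 35, 138, 19, 25, 18, 160 and 46 without vehicle replicates 1, 2, 3, 5, 6, 7, 8, 11, 13 and 15 and 47 without ATRA replicate 2. Lists ranged from 7 to 12 for MEHP, 10 to 11 for ATRA, 12 to 13 for MEHP + ATRA, 8 to 12 for MEHP + ATRA against ATRA and 5 to 10 for the interaction, which called 8 without MEHP + ATRA replicate 1, 2 or 3, 9 without ATRA replicate 1 and 10 without MEHP replicate 4.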

Other observations

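The genes named in the next paragraphs and the counts over other splits were chosen after the results were seen, and the tests of the shared MEHP and ATRA direction were written before they were run, except that of the title ranges, while the maturity score they use was chosen after the data were seen. Leydig cell and steroidogenesis genes moved apart. Of 18 tested, 1 rose and 2 fell with MEHP (1 and 2 adjusted over the list alone), 3 rose and 6 fell with ATRA (3 and 6) and 3 rose and 5 fell with MEHP + ATRA (3 and 6), with adjusted p = 0.853, 0.644 and 0.697 with an estimated correlation. Hsd17b3, which encodes the enzyme that makes testosterone from androstenedione, changed by −0.45 ± 0.08 with MEHP, −0.66 ± 0.08 with ATRA and −1.58 ± 0.09 with both (edgeR). Hsd17b1 changed by −1.09 ± 0.14 with MEHP. Fdx1, the electron donor of mitochondrial steroid hydroxylases, rose by 0.39 ± 0.09, 0.48 ± 0.09 and 1.04 ± 0.09, and Por rose by 0.68 ± 0.06 with ATRA and 0.91 ± 0.06 with both.

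Of 19 germ cell genes, 0 rose and 1 fell with MEHP (0 and 1 adjusted over the list alone), 2 and 1 with ATRA (2 and 2) and 2 and 6 with MEHP + ATRA (2 and 6), with adjusted p = 0.689, 0.92 and 0.787 with an estimated correlation. Sohlh2 (2.29 ± 0.25 and 2.56 ± 0.26) and Kit (0.67 ± 0.07 and 0.97 ± 0.07) rose with ATRA and with both, and Tdrd5 changed by −0.64 ± 0.17, −0.83 ± 0.16 and −1.57 ± 0.19 with MEHP, ATRA and both. Of 11 male germ cell differentiation genes, 3 rose and 1 fell with ATRA (3 and 1 adjusted over the list alone; adjusted p = 0.854), among them Lefty1 (1.83 ± 0.32). Of 7 Hedgehog response genes, 1 rose and 3 fell with MEHP + ATRA (2 and 3 adjusted over the list alone; adjusted p = 0.787), with Foxf1 at −2.34 ± 0.36 and Gli1 at −0.45 ± 0.07. Of 11 mesonephros genes, 2 rose and 1 fell with ATRA (2 and 1 adjusted over the list alone; adjusted p = 0.898), with Pax2 at 2.57 ± 0.24 and Wfdc2 at −0.84 ± 0.24, where the median was −0.12 and the mean 0.12. Of 13 p53 target genes, 1 rose and 3 fell with ATRA (1 and 4 adjusted over the list alone; adjusted p = 0.79), with Perp at 1.44 ± 0.22 and Bbc3 at −0.40 ± 0.09. Of 15 hypoxia and glycolysis genes, 3 rose and 1 fell with MEHP + ATRA (3 and 1 adjusted over the list alone; adjusted p = 0.787), with Adm at 1.26 ± 0.19. Of 13 erythroid genes, 0 rose and 1 fell with MEHP + ATRA (0 and 1 adjusted over the list alone; adjusted p = 0.787), and of 15 macrophage genes 0 were called with any treatment.

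MEHP and ATRA moved genes in the same direction against different vehicle libraries, with a correlation of 0.37 across genes. With the maturity score as a covariate the correlation was 0.42. The genes of the score were chosen for no difference between groups, so it cannot decide on unequal germ cell maturity of the groups. A weak retinoid effect of MEHP that scales all genes alike was argued against by the ratio of MEHP to ATRA log2 fold changes. A single ratio of 0.67 over 557 genes left a chi-square per degree of freedom of 5.01. Genes may differ in how they respond to a weak retinoid, so this test cannot decide on an effect without a common ratio. The ratio of MEHP to ATRA was 0.13 for Cyp26a1, 0.15 for Rarb, 0.22 for Dhrs3 and 0.41 for Stra8 but 1.04 for Asic4, 0.88 for Miox and 1.03 for Amh, and its median was 0.35 over 22 retinoic acid response genes. With each effect fitted only in its own range, the correlation was 0.45 over 17432 genes (0.42 without the range term). Against pooled vehicle libraries, a level difference between the title ranges shifts the MEHP and ATRA effects in opposite directions. Such a difference could only lower a positive correlation, so the test of the title ranges decided nothing. No further explanation was tested.

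The gene counts were not reached by other splits among 100 of the libraries (50 for the interaction), since only the real split, 1 of 100 or 1 of 50, gave as many. The other splits mixed libraries of the compared groups, so real differences widened the spread within their groups, and their median was 0 genes in each comparison. They also took libraries as exchangeable, so chance is not excluded, least of all for the few genes of the range and the interaction. With only the libraries of each comparison, the real and the highest other counts were 439 and 62 for MEHP, 4147 and 1692 for ATRA, 6214 and 1840 for MEHP + ATRA, 2794 and 144 for MEHP + ATRA against MEHP and 4 and 1 for the range. The interaction called 2 genes in the real split and 0 at most in the others, which bears on those 2 and not on the 6 called with all libraries. The highest other split for ATRA kept 4 of 5 ATRA libraries together and that for MEHP + ATRA 3 of 4. MEHP + ATRA against ATRA gave 730 genes and 723 in the highest other split, which set ATRA replicates 1, 2, 4 and 5 against ATRA replicate 3 with all 4 MEHP + ATRA libraries, and so parted the libraries nearly as the labels do. Chance could not be excluded for the number of lists called at the preset correlation. As many lists were called in 66 of 100 splits for MEHP (real 7, highest other 16), 23 for ATRA (11 and 15), 10 for MEHP + ATRA (14 and 18), 41 for MEHP + ATRA against ATRA (11 and 21) and 40 of 50 for the interaction (5 and 14), so the list results rest on the estimated correlation and on the members.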
